A study of Rattus norvegicus with 9 samples.

How the data were processed

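The data were transcript counts from RNA sequencing of PC12 cells, a rat cell line derived from a pheochromocytoma of the adrenal medulla that is used as a neuron-like model. There were 9 libraries in 3 groups of 3: untreated controls, cells given erastin, and cells given erastin together with PQR NPs, a nanodelivery system whose composition the labels do not describe. Erastin blocks cystine import through the cystine/glutamate antiporter and is widely used to start ferroptosis, a form of cell death driven by iron and lipid peroxidation. Doses and times are not given in the sources used here. Per the labels' protocols, poly(A) RNA was selected from total RNA with oligo(dT) beads, copied with random hexamers, amplified by PCR and sequenced as paired-end reads on an Illumina NovaSeq instrument. Whether the libraries keep the strand, and whether counting used it, is not given in the sources used here, so transcripts that overlap others on the opposite strand are uncertain. The protocol names no molecular identifiers, and floors cover counting error only.

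The authors deposited 1 table of raw counts, per the file headers with 1 row per Ensembl rat transcript and 1 column per library, in whole numbers that were not normalized. Per the submitters' processing notes, HISAT2 2.2.1 and the genome build Rnor 6.0 were used; their roles, the counting program and the annotation release are not given in the sources used here. How reads that fit several transcripts of a gene were divided is likewise not given in the sources used here, and a count of 1 transcript can therefore move with how reads were assigned among its isoforms or near-identical copies. The table held 41078 rows, of which 15951 were at 0 in every library. It pairs the transcript IDs with no gene names, and 0 of the 41078 IDs matched the gene table used here, which is built on RefSeq genes of the GRCr8 assembly. Results are therefore given for transcripts, by class of response, abundance and rank. The 32 gene lists fixed before the data were examined, with 775 entries, matched 0 IDs, so tests of gene lists were not run.

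Each column was assigned to a library by the name its title gives. Total counts ran from 34772755 to 40826754 per library. A count of 0 allows up to 3 counts, which is between 0.0735 and 0.0863 CPM (counts scaled to a common library total) per library. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries within a group was alike within sampling noise: the chi-square of their counts per degree of freedom ran from 33.8 to 77.2.

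The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, with limma 3.58.1) on the deposited counts of all 9 libraries, with TMM scaling, edgeR's own filter on low counts (17123 transcripts tested) and Benjamini-Hochberg adjustment in each comparison at an adjusted p of 0.05. The 3 comparisons were erastin against control, erastin plus PQR NPs against erastin, and erastin plus PQR NPs against control. A transcript changed with erastin was called reversed if it was also called, in the opposite direction, in the comparison of the co-treatment with erastin alone. All adjusted p-values given for transcripts come from this test. The common biological coefficient of variation was 38.3%, and the median over transcripts was 23.3%. CPM of the abundant transcripts are on TMM-adjusted library sizes, and CPM of the transcripts named by ID are on total counts. A fold against a group at 0 in all its libraries is a lower bound, computed from the mean CPM of the other group and a floor of 3 counts per library. Values per library (totals, transcripts detected, share of counts in the most abundant transcripts) were compared with two-sided exact permutation tests, whose smallest possible p for 3 against 3 is 0.1, with adjustment over 18 tests.

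The rule for naming genes, fixed before the data were examined, took those with the largest fold changes past the threshold whose libraries did not overlap between groups and whose mean in the higher group was at least 5 CPM, and skipped genes without a name. As no transcript had a name, that condition was dropped, and only the first 2 transcripts in each direction of erastin against control are printed by ID. Among the 20 most abundant transcripts, those changed 2-fold or more with erastin are described by their abundance rank, a choice made after their values were seen.

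The test was checked on simulated counts for erastin against control, made from the means of the control libraries and the totals of all libraries. Changed transcripts were drawn from those at a mean of 1 CPM or more, with 198 among the 16216 in the step. Of those changed 2-fold 46.46% were recovered, and of those changed 4-fold 69.7%, while 10 of 125 calls (8%) were false. In the data 9061 of 17123 transcripts were called, so these rates do not give the power of the real comparison. Alternatives were DESeq2 1.42.0, DESeq2's size factors or upper quartile scaling in edgeR, no filter and a stricter filter on low counts (5 CPM in 3 libraries), only the 6 libraries compared, the replicate number as a block, an adjusted p of 0.01, leaving out each library in turn and leaving out the 20 most abundant transcripts. After the data were seen, the adjusted p of 0.01 for all counts other than those of changed transcripts, thinning of every library to the smallest total and leaving out transcripts that were at 0 in 1 library and at 10 CPM or more in another of the same group were added. Figures were drawn with matplotlib 3.10.9.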

Results

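RNA sequencing of PC12 cells was used to ask what erastin, an inducer of ferroptosis with which the series sets up its PD model, changes in the transcriptome, and how far PQR NPs given with erastin counter it. Counts per transcript were available for 3 control, 3 erastin and 3 co-treated libraries. The control libraries held 37520642, 39140041 and 38206510 counts, the erastin libraries 37170587, 34994411 and 34772755, and the co-treated libraries 39292116, 40826754 and 39227880. More transcripts were detected with erastin (20696 ± 239, SD, n = 3) than in controls (19578 ± 150, SD, n = 3) or under co-treatment (19987 ± 135, SD, n = 3), and the 3 groups did not overlap. With every library thinned to the smallest total, 20669 ± 276, 19486 ± 150 and 19860 ± 128 transcripts (SD, n = 3 each) were detected. The 10 transcripts with the highest mean abundance over all libraries took 7.25% ± 0.553 (SD, n = 3) of the counts with erastin, 5.30% ± 0.379 in controls and 4.97% ± 0.246 under co-treatment. Each of the differences of erastin from the other groups so far had an exact permutation p of 0.1, the smallest that 3 against 3 allows (0.112 adjusted over 18 tests). Of the gap in that share between erastin and control, 1.953 percentage points, 1.23 came from 1 transcript, the 6th by abundance, which took 0.0433% ± 0.00503 of the counts in controls, 1.27% ± 0.141 with erastin and 0.166% ± 0.00241 under co-treatment (SD, n = 3). Without it the remaining 9 took 5.98% ± 0.428 with erastin, 5.26% ± 0.374 in controls and 4.80% ± 0.248 under co-treatment (SD, n = 3; exact permutation p 0.2 for erastin against control and 0.1, the smallest possible, for the co-treatment against erastin, not adjusted).

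The erastin libraries stood apart from the other 6, and the co-treated libraries lay nearer to the controls. Across transcripts, which are not independent replicates, Pearson's r of log2 CPM was 0.936 to 0.948 between libraries of the same group, 0.924 to 0.934 between control and co-treated libraries, 0.871 to 0.889 between erastin and co-treated libraries and 0.855 to 0.883 between control and erastin libraries. The first principal component (41.8% of the variance) separated erastin from the other groups, and the second (13%) separated control from co-treated libraries. The root mean square difference between group means was 1.349 on the log2 scale for erastin against control, 1.267 for the co-treatment against erastin and 0.809 for the co-treatment against control.

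**Figure D1:**
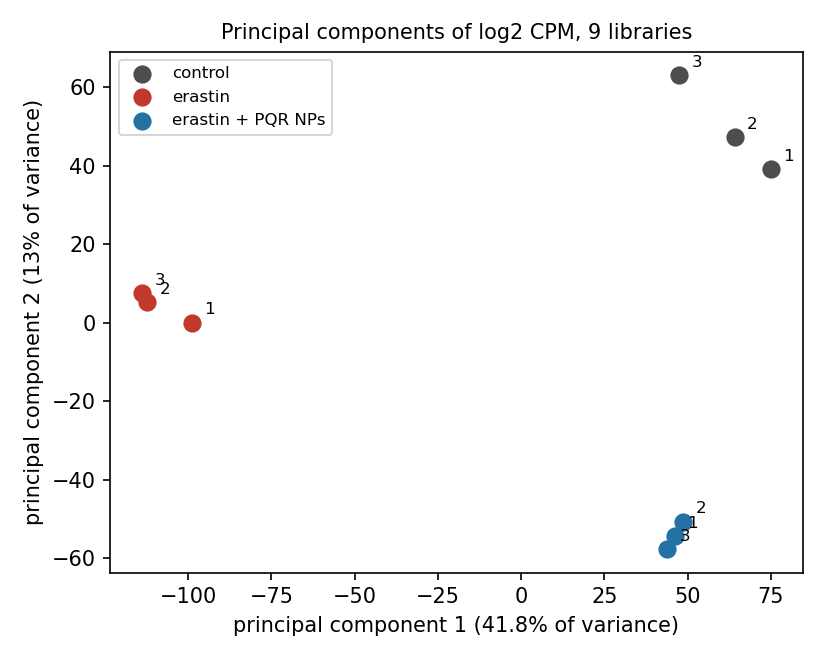
Principal components 1 (41.8% of the variance) and 2 (13%) of log2 CPM, in arbitrary units, with 1 point per library, coloured by group and marked with its replicate number. The 3 erastin libraries lie on the left, and control and co-treated libraries lie on the right and differ on component 2.

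Erastin against control asks what erastin changes in these cells. Of 17123 transcripts tested, 9061 changed (52.9%), 4558 of them higher and 4503 lower (50.3% higher, and 47.7% with upper quartile scaling). The rises were the larger changes: the median rise was 2.34-fold and the median fall 1.82-fold, and 2777 transcripts rose and 1851 fell 2-fold or more. With transcripts at 0 in a whole group set at their lower bound, 155 rose and 48 fell 16-fold or more. Of the rises, 75 started from transcripts with no count in any control library, and 24 of the falls ended with no count in any erastin library.

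The share of falls was higher among abundant transcripts. Tiers were set by the mean of the control and erastin group means, which a rise and a fall of the same size move alike, a choice made after the data were seen. Among transcripts under 1 CPM, 424 rose and 195 fell with erastin, so that falls made up 31.5% of the changes. From 10 to 100 CPM, 2450 rose and 2554 fell (51.0% falls), from 100 to 1000 CPM 603 rose and 880 fell (59.3% falls), and at 1000 CPM or more 22 rose and 38 fell (63.3% falls). With tiers set by the mean of all 9 libraries, which places transcripts on only with erastin lower than those off only with erastin, falls made up 27.6% of the changes under 1 CPM and 66.2% at 1000 CPM or more. The share of tested transcripts that changed was 22.3% under 1 CPM and 71.2% from 100 to 1000 CPM, and as the power of the test rises with the count, these shares do not rank the tiers.

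Among the 20 most abundant transcripts, 15 changed with erastin, 8 higher and 7 lower, and 4 of them changed 2-fold or more. The largest rise among these was that of the transcript of abundance rank 6, from 439 ± 52.5 CPM in controls to 12970 ± 1630 CPM with erastin (SD, n = 3 each), a 29.5-fold rise with an adjusted p of 5.6e-07 in edgeR's test. At rank 5 the transcript rose 3.56-fold, from 2431 ± 205 to 8654 ± 1820 CPM, and that of rank 14 rose 2.81-fold, from 1989 ± 206 to 5583 ± 367 CPM (SD, n = 3; edgeR adjusted p 3.3e-05 and 1.6e-05). A fall was seen for the transcript of rank 12, from 6278 ± 850 to 2979 ± 507 CPM, to 0.474 of its control level (SD, n = 3; edgeR adjusted p 0.00049).

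The rule for named features led to transcripts present in only 1 of the 2 groups compared. ENSRNOT00000084595 had no count in any control library and 11480, 12576 and 10153 counts in the erastin libraries (320 ± 35.1 CPM, SD, n = 3), at least 4080-fold higher, with an adjusted p of 7.6e-06 in edgeR's test. ENSRNOT00000003558 had no count in controls and 56.1 ± 14.6 CPM with erastin (SD, n = 3), at least 716-fold higher (edgeR adjusted p 7.5e-05). ENSRNOT00000059763 went from 43.2 ± 7.82 CPM in controls (SD, n = 3) to no count in any erastin library, at least 513-fold lower (edgeR adjusted p 0.012). ENSRNOT00000088252 went from 17.8 ± 3.39 CPM (SD, n = 3) to no count with erastin, at least 211-fold lower (edgeR adjusted p 0.036). Its call was lost when any control or erastin library was left out: the adjusted p was 0.0704, 0.0704 and 0.0626 without control replicates 1, 2 and 3, and 0.0736, 0.0744 and 0.0731 without erastin replicates 1, 2 and 3 (range over the 17 alternatives that gave it one, 0.000133 to 0.0744). DESeq2 gave it no adjusted p. The test estimates the spread over all 3 groups together, and the co-treated libraries held 0, 585 and 0 counts of this transcript. With only the 6 libraries compared its edgeR adjusted p was 0.000181, and that of ENSRNOT00000059763 was 0.000122. The counts printed by ID are of single transcripts, and a gene's other transcripts are not included in them. Both transcripts that fell were also at 0 in part of the co-treated libraries and above 10 CPM in the rest, a switch within a group that leaves the assignment of their reads uncertain.

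**Figure D2:**
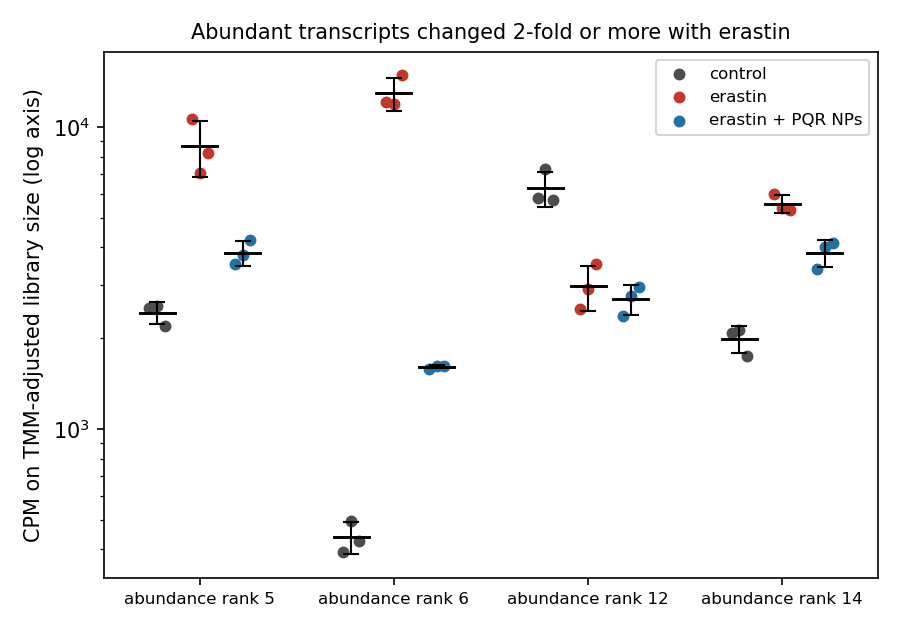
CPM on TMM-adjusted library sizes (log axis) of the 4 transcripts among the 20 most abundant that changed 2-fold or more with erastin, with 1 point per library, lines at the group means and bars of 1 SD (n = 3). The transcript of rank 6 had 439 CPM in controls, 12970 with erastin and 1610 under co-treatment, and that of rank 12 stayed near its erastin level under co-treatment.

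Erastin plus PQR NPs against erastin asks what the particles change in cells given erastin. Here 8764 transcripts changed (51.2%), 4327 higher and 4437 lower. The share of higher calls, 49.4%, was 54.8% with upper quartile scaling, so that the majority turned with the scaling. The falls were the larger changes: the median fall was 2.34-fold and the median rise 1.72-fold, with 2706 transcripts lower and 1479 higher by 2-fold or more. With transcripts at 0 in a whole group set at their bound, 126 fell and 31 rose 16-fold or more. Among transcripts under 1 CPM in the mean of these 2 groups, 67.2% of the changes were falls, and from 100 to 1000 CPM 43.9% were.

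The rank 6 transcript fell from 12970 ± 1630 to 1610 ± 19.3 CPM (SD, n = 3; 0.124 of its erastin level, edgeR adjusted p 4e-06). The transcripts of ranks 5 and 14 fell to 0.443 and 0.689 of their erastin levels, at 3837 ± 360 and 3847 ± 390 CPM (SD, n = 3; edgeR adjusted p 0.00035 and 0.0033). At 2695 ± 302 CPM, the transcript of rank 12 was not called (SD, n = 3; 0.905 of its erastin level, edgeR adjusted p 0.46). ENSRNOT00000084595 and ENSRNOT00000003558 had no count in any co-treated library, at least 4240-fold and 744-fold lower than with erastin (edgeR adjusted p 1.3e-05 and 9e-05). ENSRNOT00000059763 returned in 2 of the 3 co-treated libraries, with 1465, 1533 and 0 counts (edgeR adjusted p 0.016). This call was lost with the replicate number as a block (edgeR adjusted p 0.0534). With only the 6 libraries compared, this transcript did not pass the filter on low counts and was not tested. ENSRNOT00000088252 was back in 1 co-treated library, with 0, 585 and 0 counts, and was not called with all 9 libraries (edgeR adjusted p 0.066), while the adjusted p was 0.0385 without co-treated replicate 1 and 0.0395 without co-treated replicate 3 (range over the 15 alternatives with a fitted change and an adjusted p, 0.0385 to 0.165).

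Set beside the first comparison, 6955 of the 9061 transcripts changed with erastin (76.8%) were reversed under PQR NPs, 3501 of the 4558 that had risen and 3454 of the 4503 that had fallen. In the direction of erastin 106 moved further, 78 up and 28 down (44 at an adjusted p of 0.01), and 2000 were not called between the co-treatment and erastin. Among the 4628 transcripts changed 2-fold or more with erastin, 3857 (83.3%) were reversed. Over all 4628, reversed or not, the log2 fold change against control under co-treatment was a median 0.15 of that with erastin (interquartile range -0.05 to 0.38). It was 0.10 for those that had risen and 0.22 for those that had fallen. The 4628 were chosen by the size of their change with erastin, and both changes use the same controls. Chance errors of the erastin libraries make this ratio smaller, and those of the shared controls make it larger. Across all tested transcripts, the slope of the co-treatment's difference from control on that of erastin was 0.24. It was 0.18 after the part found in simulations of unchanged groups was subtracted. Independent lists of these lengths would share 1181 transcripts higher with erastin and lower with the co-treatment and 1138 of the opposite kind. Because both comparisons use the same erastin libraries, their chance errors are opposed as well: the covariance of the log2 fold changes was -1.36, against a mean of -0.169 over 20 simulations of unchanged groups, and the correlation across transcripts was -0.808 against -0.503. The simulations gave 0 reversed transcripts. With at most 1 transcript called with erastin in any of them, this 0 was fixed in advance and is no baseline for the overlap. As 3 libraries cannot be split so that each part keeps 2, part of the overlap can come from the shared libraries.

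The reversed transcripts that were no longer called against control, 3017 that had risen and 2736 that had fallen, carried much of the counts. The 3017 took 11.8% ± 1.1 of the counts in controls, 24.2% ± 1.3 with erastin and 11.7% ± 0.26 under co-treatment (SD, n = 3), and the 2736 took 28.9% ± 1.3, 17.4% ± 0.50 and 29.5% ± 0.15 (SD, n = 3). Another 841 were reversed in part and still called against control on the side of erastin. The 298 of these that had risen went from 1.70% ± 0.020 to 6.30% ± 0.40 and then 3.02% ± 0.024 of the counts (SD, n = 3), and the 543 that had fallen went from 8.40% ± 0.10 to 3.70% ± 0.018 and then 6.11% ± 0.050. Finally, 361 went past control to the other side, 186 that had risen and 175 that had fallen. These sets were chosen by the test on the same libraries, so their shares describe them and are no further test. The 841 were 507 without control replicate 2 and 499, 372 and 439 without co-treated replicates 1, 2 and 3, and the 361 were 146 and 227 without control replicates 2 and 3, 207, 126 and 181 without co-treated replicates 1, 2 and 3 and 633 with DESeq2.

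**Figure D3:**
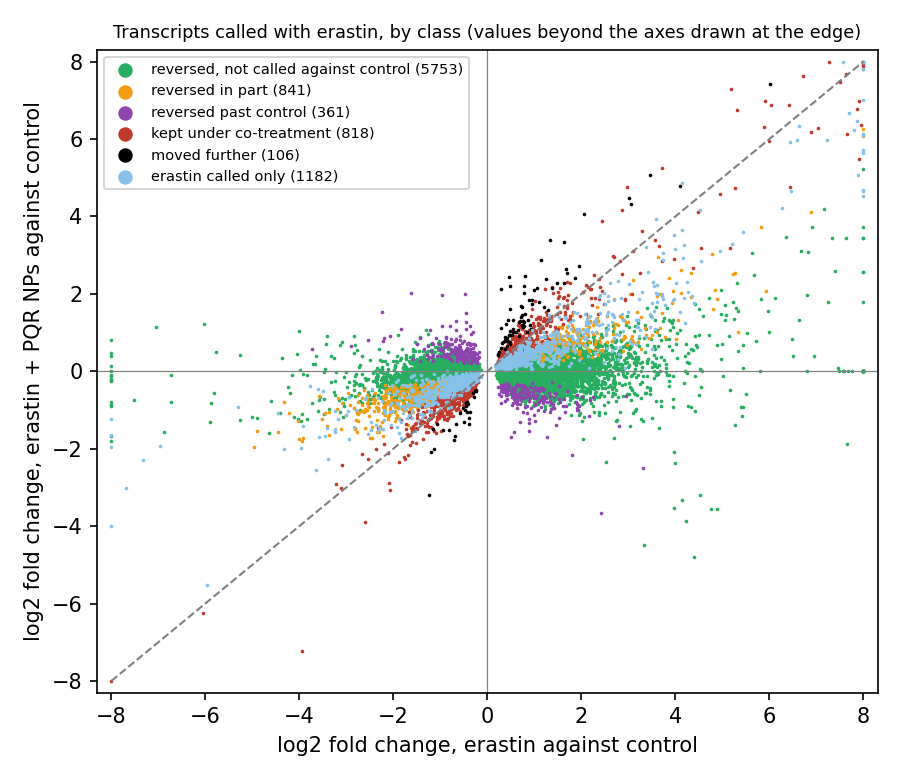
Log2 fold changes against control with erastin (horizontal axis) and with erastin plus PQR NPs (vertical axis), 1 point per transcript changed with erastin, coloured by response class, with points beyond the axes drawn at the edge and the dashed line marking equal change. The 5753 reversed transcripts that were not called against control lie along the horizontal axis, and the 818 kept under co-treatment lie along the dashed line.

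Erastin plus PQR NPs against control asks how far the co-treated cells differ from untreated ones. There were 2895 transcripts that differed (16.9%), 1318 higher and 1577 lower, of which 366 were higher and 295 lower by 2-fold or more. The share of higher calls, 45.5%, was 54.0% with upper quartile scaling and 57.4% with no filter or with the stricter filter on low counts, so that the majority turned with these settings. Under co-treatment the rank 6 transcript was 3.67-fold above its control level (1610 ± 19.3 against 439 ± 52.5 CPM, SD, n = 3; edgeR adjusted p 5.7e-05) and that of rank 14 was 1.93-fold above it (edgeR adjusted p 0.0011). The rank 12 transcript was at 0.429 of its control level (edgeR adjusted p 0.0017). At rank 5 the level was 1.58-fold above control (edgeR adjusted p 0.022), a call that was lost without control replicate 2 or 3 (adjusted p 0.0569 and 0.0542) or co-treated replicate 2 or 3 (adjusted p 0.0697 and 0.0608) (range over all its alternatives, 6.23e-05 to 0.0697).

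Of the transcripts that differed from control under co-treatment, 1765 were also called with erastin on the same side, 751 higher and 1014 lower, where independent lists of these lengths would share 350.8 and 414.7. The covariance of the log2 fold changes of both treatments against control was 0.435, against a mean of 0.166 over 20 simulations of unchanged groups compared with the same controls. The correlation across transcripts was 0.402, below the simulated mean of 0.495 (0.47 to 0.524), and part of the overlap can come from the shared controls. Within these, 818 were kept, called with both treatments against control and not called between the treatments. The 375 that were higher took 1.88% ± 0.074 of the counts in controls, 3.24% ± 0.23 with erastin and 3.33% ± 0.034 under co-treatment (SD, n = 3), and the 443 that were lower took 6.50% ± 0.34, 4.15% ± 0.17 and 4.32% ± 0.062. That the 818 were not called between the treatments does not show that they were alike there.

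The count of this comparison moved more than the others did when 1 library was left out. It was 1665 without control replicate 2 and 1853, 1325 and 1636 without co-treated replicates 1, 2 and 3. The transcripts that differed 2-fold or more moved less, with 470 to 651 against 661. The 1318 higher became 798 without control replicate 2 and 666 without co-treated replicate 2, and the 1577 lower became 867 and 915 without control replicates 2 and 3 and 848, 659 and 686 without co-treated replicates 1, 2 and 3. The 818 kept transcripts became 512 and 543 without control replicates 2 and 3 and 456 without co-treated replicate 2.

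**Figure D4:**
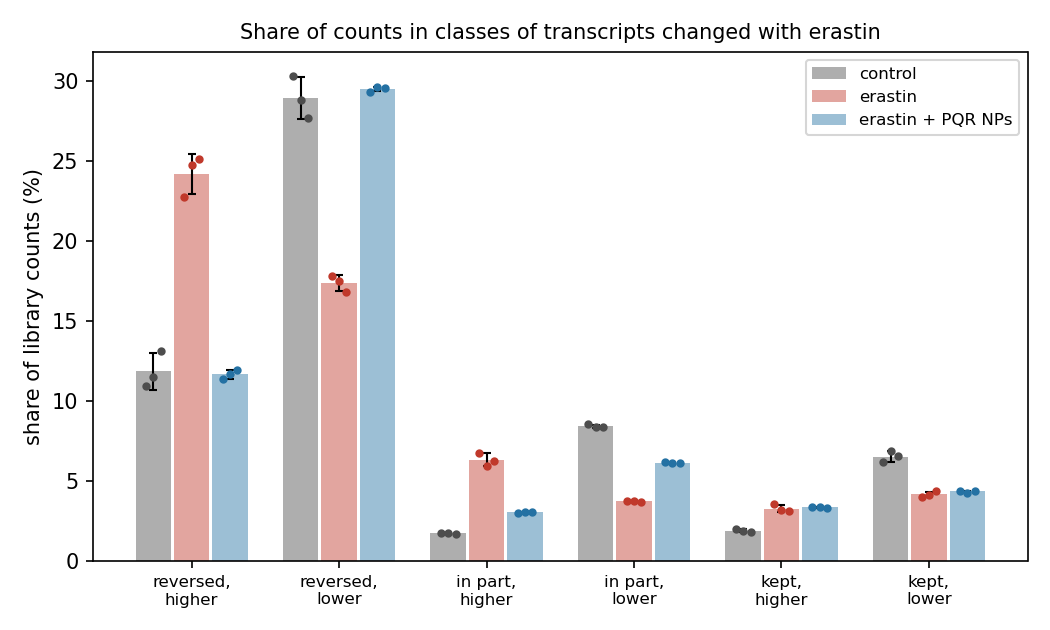
Share of each library's counts (percent) in transcripts changed with erastin that were reversed and not called against control, reversed in part, or kept, split into those higher and lower with erastin, as group means with bars of 1 SD and 1 point per library (n = 3). The reversed transcripts that had risen go from 11.8% to 24.2% and back to 11.7%, and the kept ones that had risen from 1.88% to 3.24% and 3.33%.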

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

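Chosen after the data were seen were thinning to the smallest total, leaving out transcripts at 0 and at 10 CPM or more within a group, and the adjusted p of 0.01 for counts other than those of changed transcripts. Over all alternatives and left-out libraries, the count of changed transcripts stayed within 1.5 times its value for erastin against control (6794 to 9558 against 9061) and for the co-treatment against erastin (6434 to 9269 against 8764), as did the reversed transcripts (5021 to 7367 against 6955). Those that moved further numbered 75 to 140 against 106, except for 44 at an adjusted p of 0.01. DESeq2 called 99.2%, 99.1% and 99.8% of the transcripts called in the 3 comparisons, and more besides: for the co-treatment against control 4079 in place of 2895, 1946 higher and 2133 lower. Counts for the co-treatment against control moved more: 1055 changed at an adjusted p of 0.01, 538 higher, 517 lower and 384 by 2-fold or more (against 661), where the threshold itself is lower, and 983 were lower with no filter on low counts, against 1577 (the cause was not tested). Leaving out 1 library gave 1325 to 2988 changed, 666 to 1522 higher and 659 to 1466 lower transcripts there. Without co-treated replicate 2, 44.6% of its 2895 transcripts were still called. The share of higher calls there was 45.5%, against 54.0% with upper quartile scaling, 49.8% with DESeq2's size factors and 57.4% with either other filter, so neither direction is in the majority under all of them. For the co-treatment against erastin it was 49.4%, against 54.8% with upper quartile scaling, 53.3% with no filter and 53.1% with the stricter filter, while the falls of 2-fold or more outnumbered the rises in these (2485 against 1789, 2581 against 1721 and 1920 against 1169). No scaling moved the median log2 fold change of all transcripts by over 0.1. With the replicate number as a block, 8884, 8541 and 2723 transcripts were called in the 3 comparisons. Whether the numbers pair the samples is unresolved. Of 9 pairs of libraries with the same number, 1 had a correlation of deviations over 0.1 (range -0.013 to 0.111). Pairs with different numbers ran from -0.108 to 0.076, and 5 of 9 libraries correlated best with one of their own number. ENSRNOT00000059763, at 0 in 1 co-treated library, had an adjusted p of 0.0534 with the block in the co-treatment against erastin (range over the 17 alternatives that tested it, 1.21e-05 to 0.0534). It was not tested there with only the 6 libraries compared, where it did not pass the filter on low counts. ENSRNOT00000088252, which 1 co-treated library held, was called in the co-treatment against control without that library, co-treated replicate 2 (adjusted p 0.00242, range over 17 alternatives 0.00242 to 0.714). DESeq2 gave this transcript no adjusted p. Tests of gene lists and the removal of mitochondrially encoded genes were not run, as the transcripts had no gene names. Thinning every library to the smallest total gave 9046, 8726 and 2859 calls, so depth differences of this size moved little. The 15951 of 41078 transcripts at 0 everywhere and those under the filter had no test, and whether more depth would reach them is unknown.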

Other observations

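Of the tests below, the splits of the 9 libraries and the simulations of unchanged groups for the reversal were set before their results were seen. Leaving out the 20 most abundant transcripts was chosen before the data were examined, and its use as a test after its value was seen; the other tests, with the simulated values for the 604 transcripts below, were chosen only after the result was seen.

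There were 604 transcripts that were not called with erastin and were called on the same side of both other groups under co-treatment, 315 higher and 289 lower. That they were not called does not show that erastin left them alike. Both comparisons use the same co-treated libraries, so part of the overlap can come from them. Independent lists among the 8062 transcripts not called with erastin would share 38.66 higher and 42.46 lower. Taking only transcripts not called with erastin draws both comparisons together, so these numbers are no baseline. In 20 simulations of unchanged groups at most 1 such transcript arose, but unchanged groups leave almost nothing to call, so this is no baseline. Over all 17123 tested transcripts, not the 8062 alone, the covariance of both sets of log2 fold changes was 0.219 against a simulated mean of 0.168 (correlation 0.216 against 0.501). The 315 took 1.90% ± 0.10 of the counts in controls, 1.85% ± 0.13 with erastin and 2.83% ± 0.048 under co-treatment (SD, n = 3), and the 289 took 2.48% ± 0.24, 2.50% ± 0.063 and 1.71% ± 0.058. Cells given the particles alone were not analysed here, so an effect of the particles by themselves was not separated from one that needs erastin. The 604 became 353 and 390 without control replicates 2 and 3 and 402, 268 and 341 without co-treated replicates 1, 2 and 3. The 78 transcripts that rose with erastin and rose further took 0.383% ± 0.0032 of the counts in controls, 0.669% ± 0.019 with erastin and 1.19% ± 0.025 under co-treatment (SD, n = 3).

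For each pair of groups, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many calls: 8478 for erastin against control (highest other 1), 8838 for the co-treatment against erastin (highest other 0) and 2659 for the co-treatment against control (highest other 3), in fits of those 6 libraries. With 10 splits the share cannot fall under 0.05.

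The reversal under PQR NPs was weighed against technical causes. Of 100 splits of the 9 libraries into 3 roles, 1, the real one, gave 6955 reversed transcripts. The 1 other split that kept the 3 erastin libraries together gave 6279, and the rest gave at most 1. The splits therefore argue against a chance origin only for the erastin libraries standing apart. They cannot tell the real division of control and co-treated libraries from a chance one, since only 1 other division with the erastin libraries together was drawn. The erastin libraries shared by both comparisons give a covariance between -0.18 and -0.159 in simulations and the data gave -1.36, which argues against them as the whole cause, as do 6907 reversed transcripts after thinning against depth and 6975 without the 20 most abundant transcripts against a few transcripts taking the counts. After the simulated covariance and variance were subtracted, the slope of the co-treatment's difference from control on that of erastin was 0.18 across transcripts, which is consistent with a return of most of the erastin response, as a hypothesis. Open are the treatment itself and any handling that differed between groups, since the labels give no batches, and whether PQR NPs act on the cells or lower the amount of erastin that reaches them was not tested.

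Some transcripts switched between libraries of a single group: 56 were at 0 in a library and at 50 CPM or more in another of the same group, 30 of them in controls, 17 with erastin and 27 under co-treatment (some in several groups). One failed library is argued against, since the library with the most zeros held 17.2% of them, against an even share of 11.1%. For 33 of the 56, another transcript had within-group deviations that cancelled at least 90% of theirs, more than in any of 100 permutations of libraries within groups (highest 24, median 19), which is consistent with reads being given to another transcript, likely of the same gene or a near-identical copy; a first form of the test on 87 transcripts, those at 0 and at 10 CPM or more within a group that reached 50 CPM, gave 51 with such a partner (highest of 100 permutations 40). The partners could not be named as isoforms, so this stays a hypothesis, and real switches between cultures were not tested. Of the 265 transcripts with a fitted change of 16-fold or more between erastin and control, 13 were at 0 in a library and at 10 CPM or more in another of a group, among them ENSRNOT00000059763 and ENSRNOT00000088252, both falls printed by ID, and transcripts at 0 in a whole group were not tested for it.

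More transcripts were detected in the erastin libraries than in the others. Library depth is argued against by the totals themselves: the highest of the erastin libraries, 37170587 counts, was below the lowest of the others, 37520642. Thinning takes more from the other libraries and so is no further test. After it the lowest erastin library detected 346 more than the highest other library. A few abundant transcripts are argued against, since the 20 most abundant took a larger share with erastin, by at least 0.491 percentage points (0.216 for each library's own 20), which leaves fewer counts for the rest. Stray reads as the whole cause are argued against, since transcripts with 10 or more counts after thinning were also more numerous, by at least 237; stray reads as a part of it, a shift in the makeup of the cells that survive and the treatment itself stay open.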
